A study of Mus musculus with 6 samples.

How the data were processed

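The study compared the temporal lobe of kainic acid-treated epileptic mice after 3 weeks of chow (3 mice) or of a ketogenic diet (3 mice), with 1 library per mouse. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was captured on oligo(dT) beads and fragmented, and random-primed paired-end libraries were made with an ABclonal kit. They were sequenced on an Illumina NovaSeq or MGISEQ-T7 instrument, and which library ran on which is not given in the sources used here. Per the submitters' processing notes, the tools were HISAT2 and featureCounts of Subread and the genome build was GRCm39. Versions, annotation release, strand setting and the treatment of reads with several alignments are not given in the sources used here. Genes that overlap, antisense genes and near-identical copies can therefore share reads.

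The authors deposited a table of FPKM for genes, of which 2217 were at 0 in all 6 libraries and 33862 above 0 in at least 1. A gene's FPKM values were whole multiples of a step, so whole reads were recovered for 100% of the 33862 genes above 0, with a tolerance of 0.001. They are the smallest whole numbers that give a gene's ratios between libraries. Each gene is thus known up to a factor common to all libraries, which can differ between genes and weighs on sums over genes. A gene read in 1 library only is set to 1 read there. The recovered totals ran from 39927217 to 55910355 reads, and relative depth from 0.722 to 1.011 times that of chow replicate 1. The median tested gene had 951 recovered reads per library. The limit that a count of 0 allows is taken as 3 reads and covers counting error only. Gene symbols came from a GENCODE M21 annotation of the earlier build GRCm38, matched by gene identifier, and 35175 identifiers had one (15865 of the 16009 tested). Columns were assigned to mice by name, and no column was left unassigned. Library pairs were compared by a chi-square test of their recovered reads to look for libraries deposited more than once, and none was found.

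Genes with a mean of at least 0.5 FPKM were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 0.5), with diet as the only term, two-sided, and Benjamini-Hochberg adjustment over all 16009 genes. The threshold was an adjusted p of 0.05. Errors of log2 changes are limma's standard errors, and 95% intervals use its moderated spread. FPKM values are given as mean ± SD over 3 mice. A test on recovered reads was not the main test, because the unit deposited is FPKM. All comparisons share 1 contrast, ketogenic minus chow.

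Before the data were examined, 46 gene lists were fixed for lipid and energy metabolism, PPAR signalling, neuronal activity and transmission, cell types and brain regions, stress and hormone responses. One of them, 5 sex-linked genes, was only read per library. Ribosomal protein genes, taken by symbol under a pattern also fixed in advance, made a further list. The 46 lists thus tested, each with at least 4 measured members, were compared with other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 46. Camera with an estimated correlation and fry were alternatives. The level of a list in a library is the median over its genes of the deviation from the gene's mean over the 6 libraries. Several lists share members, so they are not independent.

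The genes named were fixed by rule. The first part takes the 12 genes with the largest change per direction among those with an adjusted p under 0.05, with non-overlapping groups, a symbol that is not a predicted model and a mean of at least 1 FPKM in the higher group. As no gene passed, these places were filled by the smallest unadjusted p among genes meeting the other criteria. The second part is 23 genes reported whatever their values, and the third up to 4 members per list with the smallest unadjusted p. Some genes chosen by these rules are withheld for evaluation and left out of the text and figures.

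The alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 2 FPKM, rescaling to TPM, quantile normalization, centring on the median, robust eBayes, library quality weights, a replicate block and leaving out each library in turn. Added after seeing the data were protein-coding genes only, limma's voom on recovered reads, and scores of striatal, thalamic and choroid plexus markers as covariates. Marker lists of other tissues were also written after the leading genes had been seen.

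The fit was tested on simulated data: negative binomial reads for the 16009 genes with the real means, library sizes and within-group spread, with 100 genes changed by each fold size, in 5 simulations of the 3 against 3 comparison. Of genes changed 2-fold, 46.0% were called, and of genes changed 4-fold 80.7%. Unchanged genes made up 38 of 652 calls. With the median spread given to every gene instead of each gene's own, 85.7% and 100% were called, so the share depends on the spread assumed. Simulated genes vary independently, so this says nothing of lists of correlated genes, and in these simulations none of the 46 lists was called by chance, while a set of 24 unchanged genes shifted by a log2 change of 0.3 was called in 5 of 5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables handled with pandas 2.3.3 and numpy 2.4.6. Genome positions were not used, because the annotation at hand is of another build.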

Results

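Bulk messenger RNA was sequenced from the temporal lobe of mice made epileptic with kainic acid, a glutamate receptor agonist that provokes seizures. The sample labels give the tissue only as brain. For 3 weeks, 3 of the mice ate chow and 3 ate a ketogenic diet, a high-fat, low-carbohydrate diet that raises circulating ketone bodies. Each mouse gave 1 library, and expression was recorded as FPKM, fragments scaled to gene length and library depth. Read numbers recovered from the FPKM steps and summed over genes were 55283358, 51147869 and 39927217 for chow replicates 1, 2 and 3. Each gene is known up to a factor of its own that is common to the libraries. For ketogenic replicates 1, 2 and 3 the sums were 55910355, 44616457 and 44063309. Of 33862 genes with reads, 16009 had a mean of at least 0.5 FPKM over the 6 libraries and were tested, with a median of 951 recovered reads per gene and library. Every pair of libraries differed by far more than counting noise, with a chi-square per gene of 35.3 or more. Positions of genes are not given because the annotation used here is of another genome build than the table.

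The libraries did not separate by diet in their overall expression, and markers of brain regions set them apart. The first principal component held 46.4% of the variance and placed chow replicate 1 at -55.1, away from the other 5 libraries, which lay between -12.7 and 34.2. Chow replicate 1 had the highest level of thalamic and hypothalamic markers, 2.08 on the log2 scale against the mean of the 6 libraries, and the lowest level of excitatory neuron markers, -1.33. Striatal markers stood at 1.93 in chow replicate 2 and 1.74 in ketogenic replicate 2, and at 0.27 or below in the other 4 libraries. Choroid plexus markers stood at 0.94, 1.80 and 1.07 in chow replicate 1, chow replicate 3 and ketogenic replicate 3, and at -1.15 or below in the others. The male-specific gene Eif2s3y was read in every library, at 12.6, 12.7 and 14.5 FPKM on chow and 9.20, 9.84 and 29.3 FPKM on the ketogenic diet, while Xist, transcribed from the inactive X chromosome, did not exceed 0.109 FPKM. The other Y-linked genes Ddx3y, Kdm5d and Uty were also highest in ketogenic replicate 3, at 26.4, 4.73 and 4.15 FPKM.

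**Figure D1:**
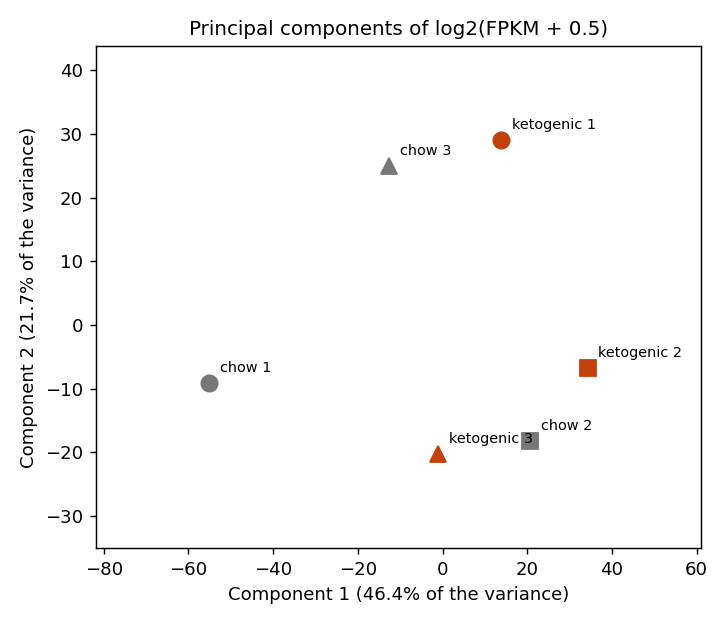
Principal components 1 and 2 of log2(FPKM + 0.5) over the 16009 tested genes, 1 point per library, grey for chow and orange for the ketogenic diet. The components hold 46.4% and 21.7% of the variance, and the 2 colours are interspersed.

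The first question was which single genes the ketogenic diet altered. The largest separations on the higher side were in heat shock proteins and in genes known from intestinal epithelium. Hspa1b (ENSMUSG00000090877), a stress-induced chaperone, measured 8.96 ± 0.502 FPKM (SD, n = 3) on the ketogenic diet and 3.09 ± 0.566 FPKM on chow, a log2 change of 1.41 ± 0.14 (SE). Its near-identical copy Hspa1a measured 2.19 ± 0.257 against 1.09 ± 0.148 FPKM, and reads of the pair may be split by the counting. Lypd8, which keeps bacteria from the colon epithelium, measured 9.42 ± 2.29 FPKM against 1.49 ± 0.468 FPKM. The colon gene Mptx1 measured 6.23 ± 1.07 against 1.59 ± 0.134 FPKM, with Zg16, Clca1, Krt19 and Spink4, all known from intestinal epithelium, at 1.03 to 1.95 FPKM against 0.171 to 0.486 FPKM. Outside these groups, Cnih3, an AMPA receptor auxiliary subunit, measured 20.2 ± 1.52 against 13.4 ± 0.482 FPKM. The interferon-inducible gene Ifitm2 had a log2 change of 0.83 ± 0.15 and the haemoglobin scavenger Hp one of 1.56 ± 0.29. The precursor of miR-132 (Mir132) had a log2 change of 1.36 ± 0.26, where overlapping transcripts could share the reads.

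On the lower side, Vegfa, the main growth factor of blood vessels, measured 16.2 ± 0.899 FPKM (SD, n = 3) on the ketogenic diet and 26.4 ± 1.62 FPKM on chow, a log2 change of -0.69 ± 0.10 (SE). The haemoglobin genes Hbb-bs, Hba-a1 and Hbb-bt had log2 changes of -2.18, -1.85 and -1.75, and paralogs of this family share reads. Myoglobin (Mb) measured 2.74 ± 1.22 against 8.80 ± 2.87 FPKM and the cardiac myosin light chain Myl3 0.835 ± 0.303 against 2.71 ± 0.711 FPKM. The other genes named on this side were the interferon-stimulated gene Isg15 (log2 change -0.72), the tight junction GTPase Rab13 (-0.61), the amino acid transporter Slc38a5 (-0.90), the isoprenoid enzyme Idi1 (-0.50), the endothelial receptor Cd93 (-0.66) and the microRNA gene Mir7664 (-0.78). By the rule that chose the 24 genes named in these paragraphs, all 3 ketogenic libraries lay on one side of all 3 chow libraries in each.

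None of the 16009 genes passed the limma test at an adjusted p under 0.05 in either direction. The smallest adjusted p was 0.220, shared by Mptx1, Lypd8 and Hspa1b, and that of Vegfa was 0.659. At an unadjusted p under 0.05 there were 861 genes, 5.38% of those tested, of which 329 were higher and 532 lower on the ketogenic diet. That split depended on scaling, with 403 higher and 410 lower after quantile normalization and 490 higher and 379 lower after centring on the median. Groups did not overlap in 785 genes on the higher and 1199 on the lower side, together 12.4% where chance gives 10%. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values.

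A further question, from the title of the series, was PPAR signalling and lipid metabolism. Pparg (ENSMUSG00000000440), the nuclear receptor PPARγ, measured 1.12 ± 0.627 FPKM (SD, n = 3) on the ketogenic diet and 0.952 ± 0.520 FPKM on chow, a log2 change of 0.15 with a 95% interval from -0.87 to 1.16. Ppara, Ppard and the coactivator Ppargc1a had log2 changes of -0.11, -0.23 and -0.28, each with overlapping groups. Of the 50 measured genes of the PPAR signalling list, 34 were lower and 16 higher, with a median log2 change of -0.18, and the list was not called (adjusted p = 0.20). Its mean, -0.08, ranged from -0.16 without ketogenic replicate 3 (adjusted p = 0.0910) to -0.01 without chow replicate 1 when a library was left out, and was 0.05 with the thalamic marker score as a covariate. Known PPAR targets went both ways. The lipid droplet gene Plin4 measured 5.97 ± 2.59 against 2.03 ± 0.820 FPKM and the lipoprotein lipase inhibitor Angptl4 1.05 ± 0.246 against 0.533 ± 0.182 FPKM. Fabp4 (0.74), Lpl (0.22) and Pdk4 (0.19) had positive log2 changes, Plin2 (-0.02), Cd36 (-0.09), Cpt1a (-0.24) and Scd1 (-0.39) had negative ones, and no gene of this paragraph passed the limma test, with an adjusted p of 0.752 or more. The Fabp4 change rests largely on ketogenic replicate 3, at 2.71 FPKM against 0.775 and 0.709 FPKM in ketogenic replicates 1 and 2. Plin4 (8.94 FPKM), Angptl4 (1.33 FPKM) and Cd36 (2.68 FPKM) were also highest in that library. The mean FPKM of Cd36 was therefore higher on the ketogenic diet (1.32 against 1.24) despite its negative log2 change. The fat cell transcript Adipoq had most reads there too (26, against 10 and 5 in ketogenic replicates 1 and 2). Whether RNA of fat contributed to these values was not tested. Cpt1c, the neuronal isoform of carnitine palmitoyltransferase, measured 14.3 ± 0.473 against 11.1 ± 0.667 FPKM, while peroxisomal Acaa1a (log2 change -0.39) and cytosolic Hmgcs1 (-0.29) were lower in every ketogenic library.

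**Figure D2:**
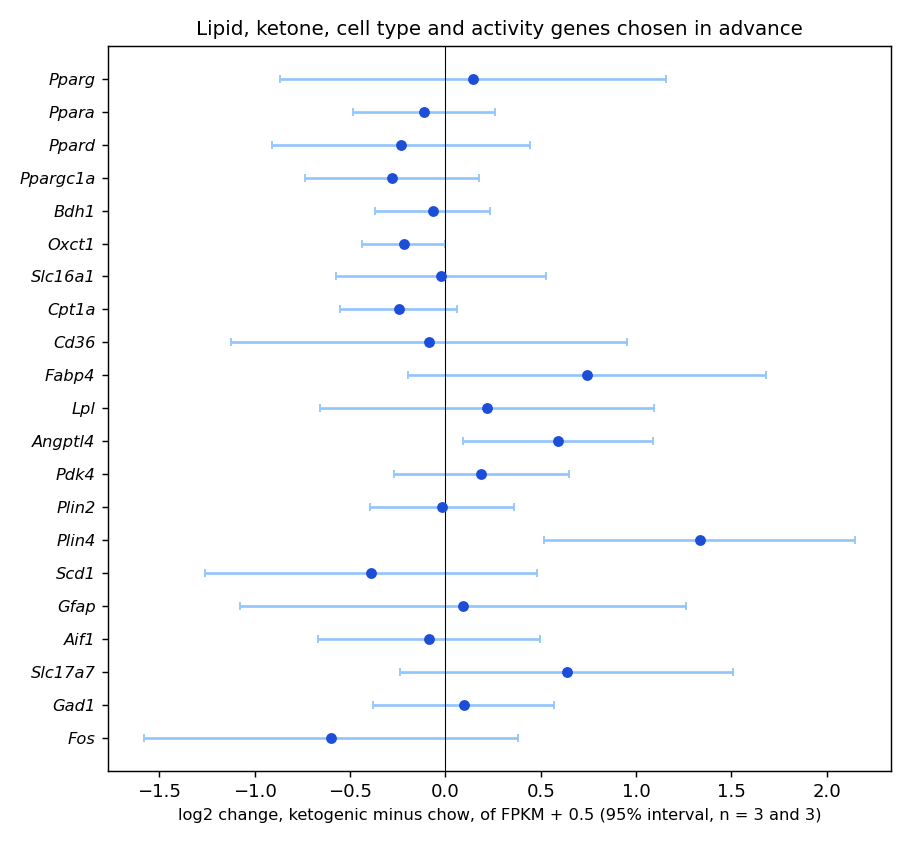
Log2 change, ketogenic minus chow, of FPKM + 0.5 for genes chosen in advance, with 95% intervals from limma (n = 3 and 3). Plin4 has a log2 change of 1.33, and the interval of Pparg spans from -0.87 to 1.16.

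Genes of fatty acid breakdown and of sterol synthesis fell as lists, and those of ketone bodies were not called. In mitochondrial fatty acid oxidation, 23 of 26 members were lower, with a median log2 change of -0.17 (camera, adjusted p = 0.00655, and adjusted p = 0.736 with an estimated correlation). Acadm, the medium-chain dehydrogenase, measured 6.92 ± 0.585 FPKM (SD, n = 3) on the ketogenic diet against 8.72 ± 0.290 FPKM on chow. In the tricarboxylic acid cycle 21 of 23 members were lower, such as Sucla2 with a log2 change of -0.28 (adjusted p = 0.00797, and adjusted p = 0.736 with an estimated correlation). In cholesterol synthesis 16 of 23 members were lower (adjusted p = 0.00529, and adjusted p = 0.736 with an estimated correlation). Cyp51 had a log2 change of -0.41 and Insig1, the sterol sensor, one of -0.49. Ketone body metabolism had 9 of 11 members lower (median -0.07, adjusted p = 0.384). Within it, Oxct1, the enzyme by which tissues use ketone bodies, measured 70.0 ± 4.34 against 81.5 ± 2.18 FPKM. Bdh1 (log2 change -0.07), the monocarboxylate transporter Slc16a1 (-0.02), its partner Bsg (-0.31) and Hmgcll1 (-0.25) belong to the same list. The fatty acid oxidation call ended without chow replicate 1 (adjusted p = 0.133) or ketogenic replicate 1 (0.106). It also ended with the thalamic marker score as a covariate (0.578) or the choroid plexus score (0.0565), and its mean, -0.17, was -0.09 without chow replicate 1. The tricarboxylic acid cycle call ended without chow replicate 1 (0.301) or ketogenic replicate 3 (0.0616) and with the thalamic score (0.459), its mean, -0.13, being -0.05 without chow replicate 1, and the cholesterol call without chow replicate 2 (0.0575) or ketogenic replicate 3 (0.0693).

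Other lists of energy and lipid metabolism did not pass. Peroxisomal lipid metabolism had 13 of 19 members lower (adjusted p = 0.231), with Scp2, Abcd3 and Cat at log2 changes of -0.22, -0.27 and -0.36. Fatty acid synthesis and desaturation had 17 of 21 lower (adjusted p = 0.0830), with Elovl5, Elovl7, Elovl6 and Fads1 at -0.46, -0.69, -0.41 and -0.20. It was called without chow replicate 2 (0.0180) or without chow replicate 3 (0.0275), while its mean, -0.18, was -0.04 without chow replicate 1. Cholesterol efflux and lipoprotein handling had 15 of 23 lower (adjusted p = 0.20), with Pltp, Npc2, Lcat and Nr1h3 at -0.52, -0.45, -0.51 and -0.30. Eicosanoid and endocannabinoid metabolism had 18 of 27 higher (adjusted p = 0.101, and 0.0491 without chow replicate 3, with a mean of 0.08 that was 0.01 without chow replicate 1), led by the lipoxygenase Alox12b at 1.25 and Ptges2, Ptgds and Hpgd at 0.16, 0.31 and -0.23. Glycolysis and glucose uptake had 12 of 23 higher (adjusted p = 0.0677), with both Aldoa entries at 0.72 and 0.20, Hk1 at 0.23 and Pfkl at 0.20. It was called without ketogenic replicate 1 (0.0441) or 3 (0.0244) and with library quality weights (0.0460), but its mean, 0.06, was -0.03 without ketogenic replicate 2. Nuclear-encoded oxidative phosphorylation had 50 of 70 lower (adjusted p = 0.0720), with Cox6c, Atp5h, Ndufs6 and Uqcrb at -0.30, -0.31, -0.27 and -0.39. It was called without chow replicate 2 (0.00679), chow replicate 3 (0.00330) or ketogenic replicate 2 (7.22e-06), without a filter (0.0370), with a filter of 2 FPKM (0.0388) and after quantile normalization (0.000261). Its mean, -0.08, turned to 0.01 without chow replicate 1. Of the mitochondrially encoded genes 10 of 13 were lower (adjusted p = 0.482, and 0.0426 without chow replicate 3). Among them mt-Nd5 measured 3268 ± 329 FPKM (SD, n = 3) on the ketogenic diet against 3643 ± 428 FPKM on chow. The genes mt-Nd3, mt-Nd4l and mt-Co3 measured 17.6, 21 and 22 FPKM against 26.9, 90.8 and 15.2 FPKM, so mt-Co3 was higher. They share sequence with nuclear copies, and their values are uncertain for that reason. The chow mean of mt-Nd4l rests on chow replicate 1, at 223 FPKM against 23.3 and 25.9 FPKM in chow replicates 2 and 3.

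Glucocorticoid-responsive genes rose as a list, and interferon-responsive genes fell. All 21 measured members of the glucocorticoid list were higher on the ketogenic diet, with a median log2 change of 0.27 (camera, adjusted p = 3.72e-08, and adjusted p = 0.736 with an estimated correlation). Its level was above that of every chow library in each ketogenic library. Fkbp5, a glucocorticoid receptor chaperone and a classical target, measured 7.42 ± 0.353 FPKM (SD, n = 3) against 5.14 ± 1.35 FPKM, and the sulfotransferase Sult1a1 8.04 ± 1.03 against 5.41 ± 0.174 FPKM. Plin4 and Angptl4 belong to this list as well. In the interferon list 23 of 24 members were lower, with a median of -0.25 and non-overlapping groups in 10 (adjusted p = 9.05e-05, and adjusted p = 0.736 with an estimated correlation). Isg15 measured 1.18 ± 0.0618 against 2.29 ± 0.309 FPKM, Ifit1 0.766 ± 0.0884 against 1.33 ± 0.134 FPKM, and Irf9 and Gbp3 had log2 changes of -0.49 and -0.79. The interferon-inducible gene Ifitm2, which is outside the list, went the other way (0.83). Both lists were called when any 1 library was left out, but the mean log2 change of the interferon list, -0.27, was -0.17 without chow replicate 1 and -0.11 with the thalamic marker score as a covariate. Its level was highest in chow replicate 1, at 0.36, the library with the highest thalamic markers. The mean of the glucocorticoid list, 0.36, was 0.39 and 0.43 in these settings.

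Heat shock and protein folding genes and circadian clock genes were called higher as lists. In the heat shock list 14 of 24 members were higher, with a median log2 change of 0.07 (camera, adjusted p = 0.00463, and adjusted p = 0.736 with an estimated correlation). Its mean, 0.14, lay above the median, with the near-identical copies Hspa1b and Hspa1a at 1.41 and 0.76. The change was thus one of some chaperones rather than of the list throughout, and the list was not tested without this pair. The endoplasmic reticulum chaperone Hspa5 measured 88.1 ± 0.266 FPKM (SD, n = 3) on the ketogenic diet against 65.7 ± 2.63 FPKM on chow, and Dnajb1 22.4 ± 1.15 against 17.0 ± 0.584 FPKM. The list also passed limma's fry test for change in either direction (adjusted p = 0.00229), the only one of the 46 lists that did. Its camera call ended without chow replicate 2 (adjusted p = 0.0654) and after quantile normalization (0.0603). In the circadian list 13 of 19 members were higher, with a median of 0.24 (adjusted p = 0.00491, and adjusted p = 0.736 with an estimated correlation). Nr1d1, the clock repressor REV-ERBα, measured 38.6 ± 4.82 against 29.9 ± 1.40 FPKM, with Cry2, Usp2 and Ciart at log2 changes of 0.36, 0.30 and 0.49. The mean of the circadian list, 0.16, was 0.09 without chow replicate 1, and with the thalamic marker score as a covariate its call ended (adjusted p = 0.284).

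Neuronal lists rose and myelin and thalamic lists fell, in step with the regional markers that set chow replicate 1 apart. Excitatory neuron markers were higher in 13 of 16 members, with a median log2 change of 0.66 (adjusted p = 0.00127), and Slc17a7, the main cortical glutamate transporter of synaptic vesicles, measured 171 ± 43.7 FPKM (SD, n = 3) against 115 ± 45.2 FPKM. Inhibitory neuron markers were higher in 14 of 19 (0.37, adjusted p = 0.0199), neocortical and amygdalar markers in 15 of 21 (0.42, adjusted p = 0.0278), neuropeptides in 18 of 24 (0.23, adjusted p = 0.0357) and synaptic vesicle and postsynaptic density genes in 21 of 29 (0.20, adjusted p = 0.000269). Among their named members, Ptk2b, Slc30a3 and Itpka had log2 changes of 0.71, 0.89 and 1.14, the interneuron genes Htr3a, Kit and Sst 0.75, 0.58 and 0.94, and the scaffold gene Shank2 0.44. Myelin and oligodendrocyte markers were lower in 24 of 24 members (median -0.54, adjusted p = 0.000119), with Ugt8a, Opalin and Enpp6 at -0.93, -0.66 and -0.66. Thalamic and hypothalamic markers were lower in 16 of 20 (median -1.25, adjusted p = 0.00529), with Zic1 at 31.8, 3.26 and 7.03 FPKM on chow and 1.49, 1.87 and 2.86 FPKM on the ketogenic diet. For each list of this paragraph adjusted p = 0.736 with an estimated correlation. Without chow replicate 1 the calls of the excitatory (adjusted p = 0.0546), inhibitory (0.301), neocortical (0.602), neuropeptide (0.301) and myelin (0.0821) lists ended. Those of the excitatory (0.106), neocortical (0.308) and thalamic (0.0501) lists ended without ketogenic replicate 1, that of the neocortical list without ketogenic replicate 2 (0.0547), and those of the inhibitory (0.179) and neuropeptide (0.132) lists without ketogenic replicate 3. With the thalamic score the calls of the excitatory (0.877), inhibitory (0.611), neocortical (0.325), neuropeptide (0.578), synaptic (0.376) and myelin (0.493) lists ended, and with the choroid plexus score those of the inhibitory (0.0579), neocortical (0.143), neuropeptide (0.0588) and thalamic (0.0543) lists. The inhibitory, neocortical and neuropeptide calls also ended after quantile normalization (0.0583, 0.0612 and 0.156), centring on the median (0.0672, 0.0926 and 0.128) and with library quality weights (0.105, 0.183 and 0.0921). A filter of 2 FPKM ended the inhibitory (0.0555) and neuropeptide (0.0555) calls, and the neuropeptide call ended without a filter (0.0544) and after rescaling to TPM (0.0554). Without chow replicate 1 the mean log2 change went from 0.58 to 0.10 for excitatory, from 0.25 to -0.000216 for inhibitory, from 0.30 to -0.04 for neocortical, from 0.30 to 0.09 for neuropeptide, from 0.20 to 0.08 for synaptic, from -0.56 to -0.19 for myelin and from -0.95 to -0.35 for thalamic genes.

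Vascular and blood lists fell. Endothelial and blood-brain barrier markers were lower in 20 of 24 members, with a median log2 change of -0.25 (camera, adjusted p = 0.00127, and adjusted p = 0.736 with an estimated correlation). Itm2a measured 21.9 ± 2.74 FPKM (SD, n = 3) on the ketogenic diet against 29.3 ± 1.17 FPKM on chow, and the VEGF receptor gene Kdr 1.30 ± 0.0458 against 2.08 ± 0.388 FPKM. Mural cell markers were lower in 12 of 14 (adjusted p = 0.00922, and adjusted p = 0.736 with an estimated correlation), with the pericyte gene Rgs5 at 22.3 ± 2.76 against 34.8 ± 5.50 FPKM. Blood cell markers were lower in 6 of 9 measured members (adjusted p = 0.00463, and adjusted p = 0.736 with an estimated correlation), 4 of them haemoglobin genes. Apln, the ligand of the apelin receptor, and Bnip3 had log2 changes of -1.07 and -0.33, but the hypoxia list to which they and Vegfa belong was not called (10 of 19 lower, adjusted p = 0.561). The mural call ended without chow replicate 1 (adjusted p = 0.121), chow replicate 2 (0.0776) or ketogenic replicate 1 (0.251), and the blood call without ketogenic replicate 3 (0.0844). The blood call also ended without a filter on low values (0.161) and with a filter of 2 FPKM (0.0721), and the mural call with library quality weights (0.105). With the thalamic marker score as a covariate the endothelial (0.0775) and mural (0.247) calls ended, and without chow replicate 1 their means went from -0.21 to -0.12 and from -0.25 to -0.13.

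Choroid plexus markers were lower in 20 of 20 members (median -0.97, adjusted p = 0.0110, and adjusted p = 0.736 with an estimated correlation), with groups overlapping in every one. Ependymal markers were lower in 11 of 12 (median -0.52, adjusted p = 0.0466, and adjusted p = 0.736 with an estimated correlation). Otx2 measured 3.47, 0.0828 and 5.97 FPKM on chow and 0.0252, 0 and 2.64 FPKM on the ketogenic diet, and the ciliary regulator Foxj1 had a log2 change of -0.88. Both calls ended without chow replicate 1 (adjusted p = 0.0780 and 0.232), chow replicate 3 (0.428 and 0.298), ketogenic replicate 1 (0.238 and 0.256) or ketogenic replicate 2 (0.220 and 0.335), and with the thalamic score (0.877 and 0.977). When a library was left out the choroid plexus mean, -1.04, ranged from -1.93 (chow replicate 2) to -0.44 (chow replicate 3), and the ependymal mean, -0.50, from -0.87 (ketogenic replicate 3) to -0.27 (ketogenic replicate 2). The ependymal call also ended with a pseudocount of 0.1 (0.0502), after quantile normalization (0.0503) and with the striatal (0.0817) or choroid plexus score (0.569). Adipocyte markers were higher in 5 of 6 measured members (median 0.22, adjusted p = 0.0390, and adjusted p = 0.736 with an estimated correlation), with the carbonic anhydrase Car3 at 1.47 ± 0.962 FPKM (SD, n = 3) against 0.184 ± 0.0661 FPKM. That call ended without chow replicate 2 (0.0575), chow replicate 3 (0.216) or ketogenic replicate 3 (0.340), and after centring on the median (0.0562). Its mean log2 change, 0.43, was 0.11 without ketogenic replicate 3 and between 0.34 and 0.52 without any other library. Ribosomal protein genes were higher in 50 of 78 (median 0.04, adjusted p = 0.0357, and adjusted p = 0.757 with an estimated correlation), with Rpl29 at a log2 change of 0.29 and Rps12 and Rps27 at -0.28 and -0.81. That call ended without chow replicate 2 (0.10), chow replicate 3 (0.632), ketogenic replicate 2 (0.380) or ketogenic replicate 3 (0.179), without a filter (0.187), with a filter of 2 FPKM (0.0721), after quantile normalization (0.657) and with a replicate block (0.0514).

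**Figure D3:**
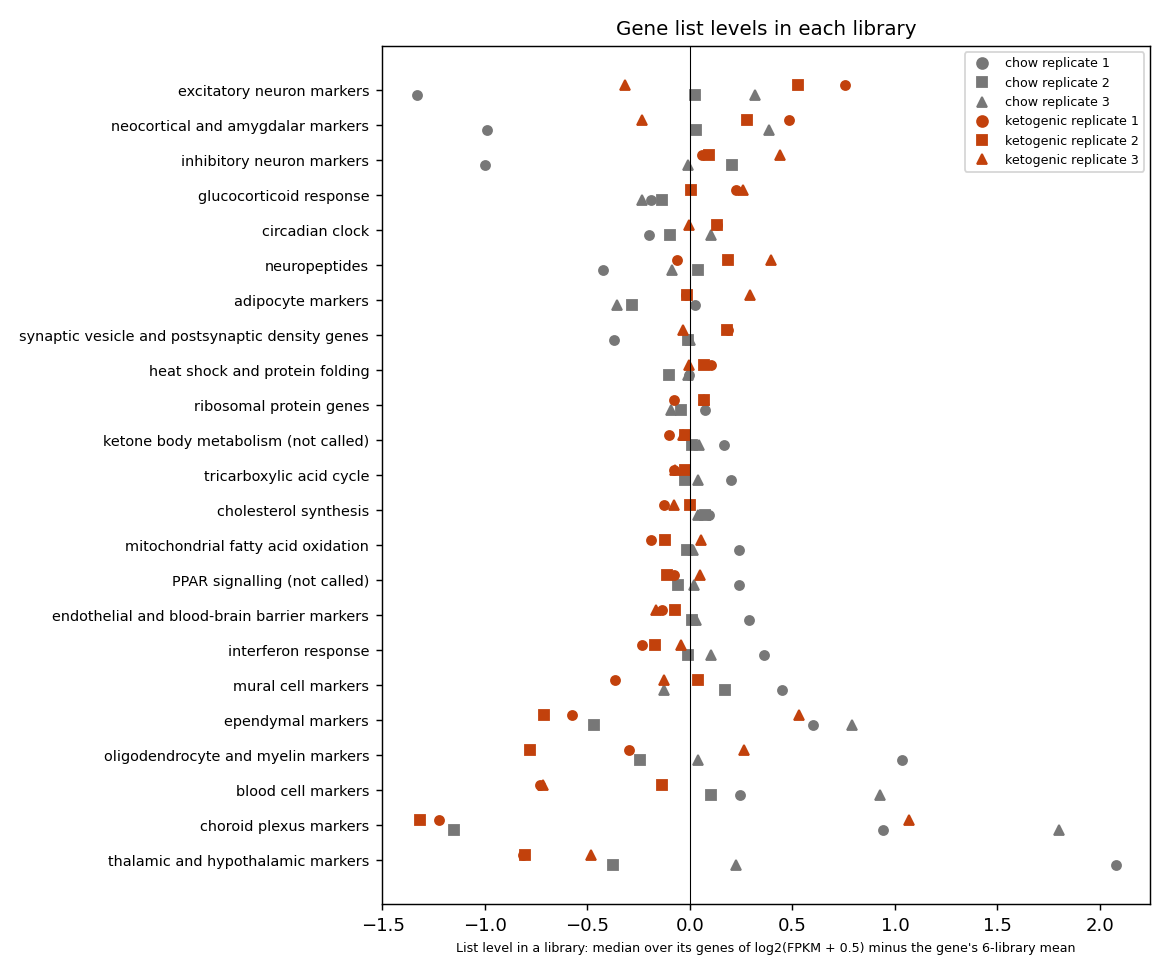
Level of each of the 21 called lists, and of the PPAR signalling and ketone body lists, in each library, as the median over the list's genes of log2(FPKM + 0.5) minus the gene's mean over the 6 libraries. Grey marks are chow and orange marks ketogenic libraries, and the glucocorticoid list separates the diets (chow -0.23 to -0.14, ketogenic 0.01 to 0.26), while thalamic markers reach 2.08 in chow replicate 1.

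Astrocyte, oligodendrocyte precursor, microglia, cytokine and immediate early gene lists were not called. Among activity-regulated immediate early genes 20 of 34 were higher (adjusted p = 0.0646), although Fos measured 9.83 ± 4.73 FPKM (SD, n = 3) on the ketogenic diet against 14.8 ± 5.96 FPKM on chow and Npas4 had a log2 change of -0.74. The list was called without chow replicate 2 (0.00521), chow replicate 3 (0.000534), ketogenic replicate 2 (0.0103) or ketogenic replicate 3 (0.0191) and by voom on recovered reads (0.0346). Its mean, 0.18, turned to -0.22 without chow replicate 1 (0.151) and to -0.05 without ketogenic replicate 1 (0.838), and its median level on chow was lowest, -0.78, in chow replicate 1. Astrocyte markers were lower in 15 of 19 (adjusted p = 0.0816, and 0.0406 without chow replicate 3, 0.0388 with a filter of 2 FPKM and 0.0121 after quantile normalization), with the water channel Aqp4 at -0.82. The mean of the astrocyte list, -0.20, was -0.09 without chow replicate 1 (0.406) and -0.02 with the thalamic score (0.877). Reactive astrocyte genes were lower in 13 of 23 (adjusted p = 0.448), with Gbp2 at -0.79 and Gfap at 36.4 ± 21.1 against 32.2 ± 12 FPKM. Oligodendrocyte precursor markers were lower in 11 of 12 (adjusted p = 0.0908, and 0.0127 without chow replicate 3 or 0.000339 without ketogenic replicate 3). Their mean, -0.25, was -0.09 without chow replicate 1 (0.632), -0.13 without ketogenic replicate 1 (0.618) and 0.07 with the thalamic score (0.432). Microglia markers were lower in 13 of 23 (adjusted p = 0.945). Without chow replicate 2 they were called higher (0.00521), with a mean of 0.12 against -0.02 over all libraries. The microglial gene Aif1 measured 1.58 ± 0.359 against 1.75 ± 0.653 FPKM. Activated microglia genes were lower in 12 of 22 (adjusted p = 0.942) and cytokines and inflammatory signalling genes in 12 of 20 (adjusted p = 0.893). The medians of these last 3 lists were negative and their camera statistics positive.

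Of the receptor and channel lists, glutamate receptors and transport had 15 of 30 members higher (adjusted p = 0.482), with Gria1 and Grik5 at log2 changes of 0.35 and 0.60. The GABA list had 14 of 24 lower (adjusted p = 0.694), with Gad1 at 59.1 ± 9.38 FPKM (SD, n = 3) on the ketogenic diet against 55.8 ± 13.2 FPKM on chow. Epilepsy-associated ion channels had 17 of 31 higher (adjusted p = 0.842), and within them the glial potassium channel Kcnj10 measured 27.8 ± 1.11 against 68.1 ± 39.6 FPKM. The mean log2 changes of the glutamate and channel lists were negative, -0.04 and -0.05, against positive medians. Hippocampal markers had 13 of 23 higher (adjusted p = 0.179), and were called higher without chow replicate 1 (0.0254) or ketogenic replicate 2 (0.00107) and with library quality weights (0.0156) or the thalamic score (0.0151). Their mean, 0.02, turned to -0.23 without chow replicate 2, -0.27 without ketogenic replicate 1 and -0.02 without ketogenic replicate 3. Striatal markers had 17 of 22 higher (adjusted p = 0.190), and were called without chow replicate 2 (7.20e-06) or ketogenic replicate 1 (0.000433) and with a replicate block (0.00530). Their mean, 0.26, turned to -0.33 without chow replicate 1, -0.16 without chow replicate 3 and -0.50 without ketogenic replicate 2. The antioxidant response had 13 of 23 lower (adjusted p = 0.842), with Hmox1 at 0.55. The integrated stress response had 10 of 17 higher (adjusted p = 0.329) and fibroblast and meningeal markers 10 of 18 lower (adjusted p = 0.706, mean 0.14 and median -0.02).

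In all, 21 of the 46 lists were called by camera with a preset correlation of 0.01, 10 higher and 11 lower, and without chow replicate 1 the number was 12. With an estimated correlation, or by fry's test for a shift in 1 direction, the number was 0. The estimated correlation of the 21 called lists was above the preset in each, from 0.0380 (cholesterol synthesis) to 0.968 (choroid plexus). It was 0.0938 for the glucocorticoid, 0.366 for the interferon and 0.964 for the myelin list. The preset thus treats these genes as more independent than they were here, which makes its adjusted p too small. After quantile normalization 5 lists were higher and 12 lower, and after centring on the median 6 and 11. Splits of the 6 libraries that mix the diets called 8 to 21 lists at the preset correlation, so many calls arise without a diet contrast. No member of any list passed over all genes tested. Adjusted over the list alone, 12 members passed: Hspa1b, Hspa1a, Hspa5, Dnajb1 and Pdia4 among heat shock genes, Hbb-bs, Hbb-bt and Hba-a1 among blood cell markers, and Isg15, Idi1, Car3 and Vegfa in the interferon, cholesterol synthesis, adipocyte and hypoxia lists. Pdia4 (log2 change 0.43) was named after its value was seen.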

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

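The tests of this part were chosen after the leading genes had been seen. Outside the tested genes, 2 transcripts of white fat were read on the ketogenic diet alone. Adipoq, which encodes the fat cell hormone adiponectin, had 41 recovered reads over the 3 ketogenic libraries (10, 5 and 26) and 0 over the 3 chow libraries. Cfd, which encodes adipsin, likewise had 41 (8, 6 and 27) against 0. Leptin (Lep) had 237 reads against 6, Cidec 62 against 2 and Plin1 60 against 10, whereas the fat genes Retn (66 against 75) and Aoc3 (207 against 182) were alike. With a limit of 3 reads for a count of 0, Adipoq and Cfd lay above the level the chow libraries allow.

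The same libraries held transcripts of intestine, and 14 of 23 heart muscle markers were lower in each of them than in every chow library. Summed reads of 30 colon and intestine markers, as RPM (reads scaled to library depth), came to 58.9, 63.5 and 87.2 on the ketogenic diet against 23.8, 24.4 and 29.7 on chow. Among the markers not looked at when the pattern was first seen, 14 of 15 intestine markers were higher on the ketogenic diet and 11 of 12 heart markers higher on chow. That tally counts any difference of means, such as Fabp3 at 62.9 RPM on chow and 60.4 RPM on the ketogenic diet. A candidate explanation is RNA or reads carried over from other tissues. The tally comes from the same libraries and cannot favour it, as related markers would move together under other explanations too. Of all markers, 7 of the 30 intestine markers and 14 of the 23 heart markers had a mean of 1 FPKM or more in these libraries. Depth does not account for the pattern, as the lowest ratio of a ketogenic to a chow library in intestine RPM was 1.98. Summed RPM separated the diets in 3 of the other-tissue lists (intestine, white fat, erythroid). The heart muscle sum overlapped between the diets, and it holds Ryr2, at a mean of 237 RPM on chow and 239 RPM on the ketogenic diet. Transcription in the brain itself could also give these differences, and the 2 explanations cannot be told apart.

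The remaining marker lists of other tissues did not separate the diets in summed RPM. The ketogenic to chow ratio was 0.896 for Paneth cells and small intestine, 0.780 for heart muscle, 0.815 for skeletal muscle, 0.438 for liver, 0.853 for kidney, 1.01 for lung, 1.13 for pancreas, 1.35 for testis, 0.997 for skin, 1.16 for spleen, 1.01 for retina and 0.404 for choroid plexus. Liver and choroid plexus sums were both high in chow replicates 1 and 3 and ketogenic replicate 3, and their ratios hang on these libraries. Liver RPM was 1618, 215 and 2523 on chow and 180, 136 and 1589 on the ketogenic diet. Choroid plexus RPM was 1156, 27.0 and 2565 against 15.8, 13.4 and 1484. The 2 sums moved together, so the liver ratio cannot be read as that of a separate tissue. The Paneth sum was 41.1 RPM in ketogenic replicate 1 against 12.1 and 20.3 RPM in ketogenic replicates 2 and 3. The spleen sum was 34.8 RPM in chow replicate 3 against 12.8 and 14.8 RPM in chow replicates 1 and 2. The ratio was 0.191 for erythroid genes, 2.57 for white fat and 2.69 for intestine.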

How the results depend on the processing

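The added settings named here were chosen after seeing the data. No setting called a gene in either direction by limma, including voom on recovered reads (smallest adjusted p 0.674, with 857 genes at an unadjusted p under 0.05), and leaving out each library gave 0 to 0. The smallest adjusted p of any setting was 0.0797, with the choroid plexus score, followed by 0.0869 with library quality weights. Correlations of same-numbered deviations were -0.0373, 0.480 and -0.215, which shows no pairing of the mice throughout the replicate numbers. It cannot exclude one, because each diet has 3 libraries and the value of replicate 2 was the highest of any chow and ketogenic pair. With the replicate block 0 genes and 21 lists were called. Under that block the ribosomal call ended (adjusted p = 0.0514, mean log2 change 0.0330) and the striatal list gained one (0.00530). Lists called fell from 21 to 0 with an estimated correlation and to 0 by fry, and to 9 with the thalamic score. Leaving out 1 library gave 12 (chow replicate 1) to 24 (chow replicate 3). Ribosomal protein genes, with a mean log2 change of 0.03, lost their camera call without a filter (mean 0.0165, adjusted p = 0.187). They also lost it with a filter of 2 FPKM (mean 0.0329, adjusted p = 0.0721) and after quantile normalization (mean 0.0126, adjusted p = 0.657). With an estimated correlation (adjusted p = 0.757) and by fry (adjusted p = 0.811) they were not called either, at a mean of 0.0330. Their mean ranged from -0.00615 to 0.0845 without 1 library. With the thalamic score the camera statistic turned for 16 of 45 lists, of which 6 were called on either side, and the mean log2 change of 14 turned. Among those 6 the mean turned for immediate early genes (-0.32, adjusted p = 0.00861), excitatory (-0.14), neocortical (-0.16) and myelin markers (0.0401), and shrank to near 0 for choroid plexus (-0.00596) and ependymal markers (-0.0121). The cause was not tested. Over all settings, 357 of 480 values of the 21 called lists kept direction and call, 118 lost the call and 5 turned. Of 574 values of the other 25 lists, 31 became calls and 1 turned with a call. None of 3346 values of the 212 named genes became a call, and 49 changed sign.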

Other observations

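Planned in advance were the fits that leave out 1 library, camera with an estimated correlation, and the other splits for counts of genes and of called lists. The remaining tests of this part, and the shares taken from the planned fits, were chosen after the results were seen. The prediction on time of day was written before its value was computed but after the circadian list had been seen.

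Most regional and cell type lists moved less with the diet without chow replicate 1 than without any other library. Choroid plexus and ependymal markers did not, with means nearest 0 without chow replicate 3 (-0.44) and without ketogenic replicate 2 (-0.27). Without chow replicate 1 the median share of the mean log2 change left over 11 lists of cell types and regions was 0.367, from -0.14 in neocortical to 0.76 in choroid plexus markers. Whether chow replicate 1 alone gives the pattern cannot be told. With the thalamic marker score as a covariate, 0 of the other 10 lists stayed called. A different amount of thalamus in the dissected tissue could give this. The level of the thalamic list was itself lower in every ketogenic library (-0.81, -0.81 and -0.48) than in every chow library (2.08, -0.38 and 0.23). Because these markers followed the diet, the score would also take up an effect of the diet, so it cannot decide between the explanations. An effect of the diet on myelin or neurons stays open as well, since it was not tested apart from tissue make-up.

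The glucocorticoid and interferon lists stayed called, with a highest adjusted p of 0.0278 at the preset correlation, over 9 settings that left out a library or added a marker score, but neither was called with an estimated correlation (adjusted p = 0.736 for both). The lowest share of the mean log2 change left in those settings was 0.835 for the glucocorticoid list and 0.428 for the interferon list. For the glucocorticoid list this argues against the make-up of any 1 library, or of the 3 scored regions, as its whole cause. For the interferon list that stays open. A difference in other cell types, or one shared by all libraries of a diet, cannot be removed by these settings and was not tested. Without the fat-expressed members Plin4, Angptl4 and Pdk4 (Lcn2 was not among the measured ones) the mean of the glucocorticoid list was 0.30 against 0.36. Because all 21 measured members were already known to be higher, this shows only that the change was not confined to these members. Whether carried-over RNA of fat or another tissue reached the remaining members was not tested. Collection at different times of day is open: evening clock genes were higher by 0.22 and morning clock genes lower by 0.04, a difference of 0.253, but the libraries of the 2 diets overlapped. An effect of the diet, stress or handling was not tested.

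The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes higher and 0 lower, and so all 10 splits gave as many. The highest other split called 26 genes in both directions together, that of chow replicates 1 and 3 and ketogenic replicate 3 against the rest. That split parts the libraries with high choroid plexus markers from the others, which points to a structure of the samples. For lists called, 2 of the 10 splits gave as many as the real 21, the highest other also 21. The splits that mix the diets called 8 to 21 lists. The number of lists called thus does not set the diets apart from other groupings of these libraries. For genes at an unadjusted p under 0.05, 4 splits gave as many as the real 861, the highest other 1860. The absolute median log2 change of the glucocorticoid list was 0.27 in the real split and at most 0.37 in another, with 2 splits as large, and that of the interferon list 0.25 and at most 0.27, with 2 splits as large.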
